A study of Mus musculus with 8 samples.

How the data were processed

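Pancreatic islets of C57BL/6J mice were cultured for 72 h in medium with 20 mM glucose (high glucose) or 7.5 mM glucose (low glucose), and their RNA was sequenced, with 4 libraries per group per the labels. Per the labels' protocols, libraries were made with the NEBNext Ultra RNA kit. Per the submitters' processing notes, STAR 2.5 was used with the mouse build mm10 (GRCm38), HTSeq 2 is named among the tools, and DESeq2 is named without a version. The strand setting, the annotation release and the treatment of reads that map to several places are not given in the sources used here. Where a gene has near-identical copies or overlaps another gene, its reads may have been split, dropped or shared, so its values are uncertain. Of 166 named genes, 35 overlap another tested gene, as was found after the data were seen. Among them are Ddit3, Txnip, Iapp, Pdx1, Slc2a2, Itgad, Slc5a10, Cox6a2, Fam196a, T2, Creb3, Eif2ak3, Psph, Atf5, Hars, Uso1, Kdelr3 and Arcn1. The others include Trpm5, Pfkfb2, Elovl1, Acsl3, Ccnd1, G6pdx, Junb, Crem, Pde10a, Irf7, Bid, Casp9, Ttr, Krt8, Eng and Alas2.

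A single deposited table lists 27534 Ensembl genes, and none of its rows stands for anything other than a gene. Per the file headers, it holds the authors' read count per gene and library, which are whole numbers and were not normalized. The table also holds a deposited signal per gene and library, which equals the count divided by 1 size factor per library. The authors' FPKM equals the count divided by the gene length listed in the table and by 1 total per library. The deposited log2 fold change and p-value columns are the authors' own comparison of high with low glucose. Its adjusted p is listed as 1 for 10703 genes, which includes genes that such a test leaves without a value. Of the gene identifiers, 27523 are in GENCODE M21 (GRCm38), and 26778 of these have the same chromosome, start and end there. Coordinates below are those of the deposited table.

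The counts were tested with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by TMM, and genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 15442 genes. A quasi-likelihood model with the group as its only term was fitted over all 8 libraries, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Fold changes are high over low glucose, standard errors are the log2 fold change divided by the square root of its F statistic, and CPM values are counts scaled by the TMM-adjusted library size. Gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where stated. The 38 lists cover the unfolded protein response, the secretory pathway, β-cell function, metabolism, growth, stress and 11 other cell types. The 37 lists with at least 3 measured genes were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and adjusted over the lists. The preset test assumes the same correlation for every list, so one estimated from each list was used as an alternative, and fry as another. Both were run without the replicate block, so the estimated correlation may include differences between same-number pairs. With the block, lists were tested with the preset correlation only. Members past the threshold were counted over all genes tested and also adjusted over the list alone. Aldoa enters the glycolysis list as 2 gene identifiers with the same symbol.

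The text names a panel of 16 genes whatever their result, the 8 protein-coding genes with the largest increase and the 8 with the largest decrease among those that passed, reached 5 CPM and did not overlap between groups, and from each list described up to 4 passing members with the smallest adjusted p and up to 2 that passed in the opposite direction. For cell type lists the 2 most abundant members are named as well. Any gene named outside this rule was chosen after its values were seen.

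Total counts were between 19543045 and 24949515 per library, so that 3 counts correspond to 0.120 to 0.154 CPM. That floor covers counting error only. Any 2 libraries differed by at least 14.2 in chi-square per gene, far beyond sampling noise, so no library was a copy of another. The same pipeline was tested on simulated counts with the means, library sizes and dispersions of the high against low glucose comparison and 200 genes changed by known folds. Of 15220 genes tested there, 43.9% of the genes changed 1.5-fold, 71.2% of those changed 2-fold and 95.2% of those changed 4-fold were called, with 6 false calls among 141. In the same simulation a list of 30 genes changed 1.5-fold gave a camera p of 1.13e-28 and an unchanged list of 30 gave 0.887. Genes were drawn independently there, so this does not show how camera performs on lists whose members vary together.

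The labels number the libraries 1 to 4 in both groups without saying what a number stands for, and nothing says whether the libraries come from separate animals or cultures. P-values therefore measure only the spread between these libraries, which may be technical. After removal of the group means, same-number libraries correlated in every pair (Pearson r across genes, which are not independent replicates, from 0.101 to 0.475), and 7 of the 8 libraries correlated best with the library of their own number. The exception was low glucose replicate 1, which correlated with high glucose replicate 4 at 0.207, above 0.101 with high glucose replicate 1. The numbers were treated as pairing the libraries, an assumption that is weakest for number 1. The fit without the pairing is reported, as planned, and the fit with the replicate number as a block is given beside a result where it changes a call or moves a count by more than 1.5 times.

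Alternatives to this fit were DESeq2 size factors, library size alone, the DESeq2 1.42.0 Wald test, limma-voom, other filters on low counts, protein-coding genes only, other thresholds, the 20 most abundant genes left out, offsets from smooth trends on gene length or GC content, the replicate block, and each library left out in turn. Alternatives on a pseudocount did not apply, since counts were available. Gene length and GC content offsets combined with the block, both libraries of a number left out, and the acinar share of each library as a covariate were added after the data were seen. Figures were drawn with matplotlib 3.10.9.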

Results

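The data are read counts per gene from bulk RNA sequencing of isolated mouse islets, the endocrine clusters of the pancreas, most of whose cells are insulin-producing β cells. Of the 8 libraries, 4 came from islets kept for 72 h in 20 mM glucose and 4 from islets kept in 7.5 mM glucose. The series concerns IRE1α, a sensor of protein folding in the endoplasmic reticulum (ER) that Ern1 encodes, and the size of the Golgi during early β-cell compensation. The comparison of the 2 glucose concentrations asks which transcripts differ after prolonged high glucose. High glucose libraries held 20516328 to 24905499 counts and low glucose libraries 19543045 to 24949515. The insulin genes Ins1 and Ins2 together took 17.2% to 22.7% of the counts of a library.

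In high glucose, 28 of 30 genes of ER protein folding, 15 of 28 of the COPII coat, 21 of 30 of the COPI coat and 37 of 38 of cell proliferation rose. With an estimated correlation, run without the replicate block, the lists' adjusted p was 0.132, 0.0295, 0.300 and 0.144, so that only the COPII list kept its call. Several genes of β-cell identity and glucose sensing fell (15 of 35, adjusted p = 0.561 for the list with an estimated correlation), as did the immediate-early gene Egr1. Of 15442 genes tested with edgeR, 3854 changed, of which 2023 were higher and 1831 lower in high glucose. A change of at least 2-fold was seen for 737 genes, 534 of them higher and 203 lower. Of all tested genes, 4218 had no overlap between the 4 high and the 4 low glucose libraries, which chance gives for 2.86% of genes, and 3490 of these were among the genes that changed. With the replicate block, the count of genes changed was 5779, the count of genes higher in high glucose 2917 and the count of genes lower in high glucose 2862. With library size alone as scaling, 37.8% of the changed genes were higher, against 52.5% with TMM scaling.

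**Figure D1:**
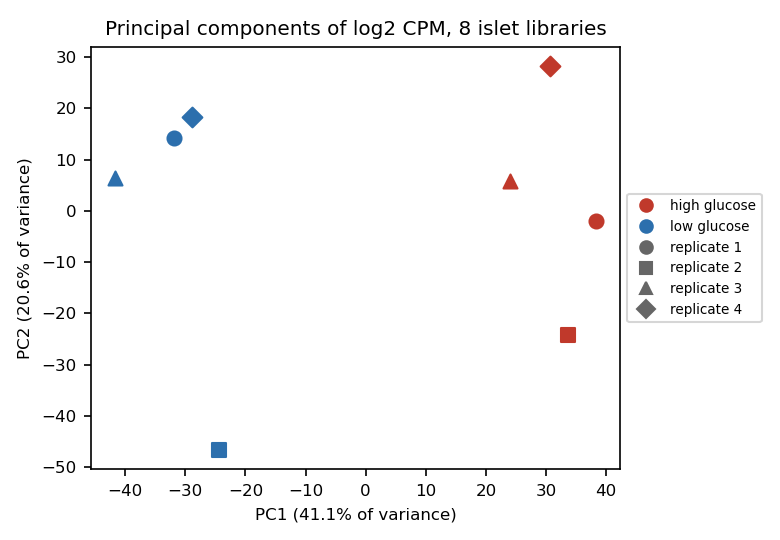
Position of the 8 libraries on the first principal components of log2 CPM (x axis PC1, y axis PC2, with the percentage of variance on each axis), coloured by glucose and shaped by replicate number. PC1 (41.1% of variance) separates high from low glucose, and on PC2 (20.6%) low glucose replicate 2 lies at -46.61, with high glucose replicate 2 next at -24.25.

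The transcript of Txnip, an inhibitor of thioredoxin induced by glucose (ENSMUSG00000038393, GRCm38 chromosome 3, 96557957 to 96561883), rose 5.57-fold, from 181 ± 21.9 to 1008 ± 89.9 CPM (mean ± SD, n = 4 per group here and below). The largest increases that met the naming rule were those of Itgad, an integrin subunit (27.3-fold), Csn3, a milk casein (22.1-fold), Zdhhc22 (14.4-fold), F13a1, a coagulation factor subunit (14.3-fold), Slc5a10, a sugar cotransporter (12.6-fold), Dapl1 (12.5-fold), Cox6a2, a muscle isoform of cytochrome c oxidase (10.5-fold), and Pdyn, which encodes the opioid precursor prodynorphin. Pdyn reached 829 ± 151 CPM in high glucose against 82.2 ± 17.5 CPM in low glucose, a 10.1-fold difference. Mean levels of Itgad, Csn3 and F13a1 in low glucose were 0.417, 0.491 and 0.336 CPM, so their folds rest on few reads. Cox6a2 lies inside Itgad on the opposite strand, so that with the strand setting not given reads may be shared and the values of both are uncertain. Slc5a10, Fam196a and T2 overlap Fam83g, Dock1 and Sft2d1, and their values are uncertain as well. The largest decreases were those of Fam196a (11.1-fold), T2 (7.12-fold), Egr1 (6.12-fold), the cannabinoid receptor gene Cnr1 (6.08-fold), Cib3 (5.90-fold), the potassium channel gene Kcng3 (4.78-fold), Reln, which encodes the matrix protein reelin (4.31-fold), and Fmo2 (4.14-fold). The adjusted p of these 16 genes was at most 0.0018 in edgeR, and all 16 kept their direction and call under each other scaling, tool, covariate and left-out library run for them.

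**Figure D2:**
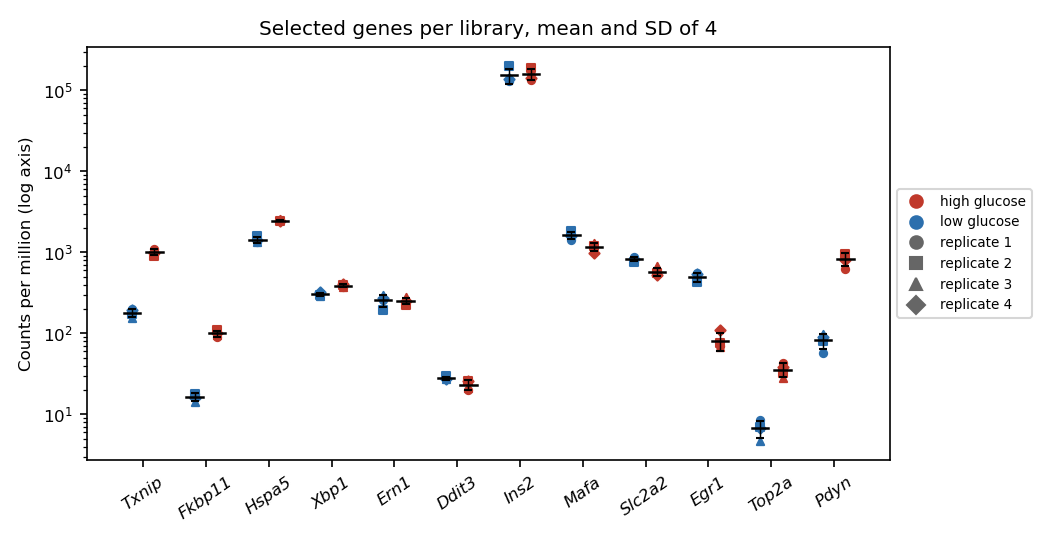
CPM (y axis, log scale) of 12 genes (x axis) in each library, blue for low and red for high glucose, with marker shape for replicate number and black bars for mean and SD of 4. Txnip, Fkbp11, Hspa5, Xbp1, Top2a and Pdyn lie higher in all high glucose libraries, Mafa, Slc2a2 and Egr1 lower, while Ern1 and Ins2 overlap. Ddit3 also lies lower in all high glucose libraries, though it did not pass in edgeR (adjusted p = 0.078).

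Transcripts for ER protein folding rose almost without exception. Of 30 measured ER chaperones and folding enzymes, 28 rose, none fell and 2 did not pass (29 rose adjusted over the list alone), with a median log2 fold change of 0.84. Fkbp11, a peptidyl-prolyl isomerase of the secretory pathway (ENSMUSG00000003355, chromosome 15, 98724366 to 98728198), rose 6.08-fold from 16.4 ± 1.76 to 100 ± 8.54 CPM. Creld2 rose 2.54-fold, Dnajb11 2.08-fold, and Dnajc3, a co-chaperone of BiP, 1.86-fold. Hspa5, which encodes BiP itself (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547), rose 1.73-fold from 1431 ± 118 to 2475 ± 60.8 CPM, and Dnajb9 rose 1.82-fold. Of 44 genes of ER translocation and ER-associated degradation (ERAD), 37 rose and none fell (39 adjusted over the list alone), with a median log2 fold change of 0.61. Among them were Derl3, an ERAD channel component (5.76-fold), Sec11c, a signal peptidase subunit (2.57-fold), Edem2, a mannosidase-like ERAD factor (2.23-fold), and Ssr3, a subunit of the translocon-associated complex (1.90-fold). The camera test with preset correlation gave adjusted p = 6.97e-22 and 9.89e-22 for these lists, and adjusted p = 0.132 for both with an estimated correlation. No member of these lists was lower at an unadjusted p under 0.05 in edgeR, and DESeq2 and limma-voom called none lower. Acinar marker genes took 0.486% to 2.72% of counts in high glucose and 0.196% to 1.64% in low glucose, and their share was higher in high glucose in each same-number pair.

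The transcript of Ern1 (ENSMUSG00000020715, chromosome 11, 106394650 to 106487852) was at 253 ± 22.5 CPM in high and 257 ± 43.4 CPM in low glucose, a log2 fold change of -0.02 ± 0.12 (SE) with adjusted p = 0.913. Xbp1, whose mRNA IRE1α splices, rose 1.28-fold, and the other members of the list of 10 unfolded protein response sensors and transcription factors that rose were Atf6b (1.21-fold), Creb3 (1.22-fold) and Eif2ak3, which encodes the sensor PERK (1.36-fold). That list was not called as a whole (median log2 fold change 0.13, adjusted p = 0.144; 4 rose both over all genes and adjusted over the list alone, and with the replicate block 5 rose and 1 fell). At an unadjusted p under 0.05, 1 member was lower in edgeR, and DESeq2 and limma-voom called none lower. Its count of 4 was 1 without low glucose replicate 1 and 2 without high glucose replicates 3 or 4 or low glucose replicates 3 or 4. Eif2ak3 did not pass without high glucose replicates 1, 3 or 4 or low glucose replicates 1, 2 or 3 (adjusted p up to 0.145), nor with library size alone (0.142). Creb3 had adjusted p of up to 0.072 without high glucose replicates 2 or 4 or low glucose replicates 1, 3 or 4, and Atf6b of up to 0.0553 without high glucose replicate 3 or low glucose replicates 1 or 4. Gene counts do not show how much of Xbp1 was spliced.

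Genes downstream of PERK and ATF4 rose in part. Atf4 rose 1.45-fold, and 14 of the 31 measured PERK-ATF4 targets rose, including Psat1 (2.49-fold) and Psph (2.01-fold), enzymes of serine synthesis, Chac1 (1.83-fold) and the translation inhibitor gene Eif4ebp1 (1.79-fold). Atf5, a transcription factor, fell 1.26-fold, the only member to fall. Adjusted over the list alone 14 rose and 2 fell, and 4 fell with the replicate block, 3 with library size alone and 2 without low glucose replicate 2. Ddit3, which encodes the pro-apoptotic factor CHOP, had a log2 fold change of -0.26 ± 0.10 (SE) with adjusted p = 0.078, and adjusted p = 0.0183 with the replicate block and 0.0207 with library size alone. The list had a median log2 fold change of 0.49 with adjusted p = 7.63e-05, and adjusted p = 0.263 with an estimated correlation. Of 20 aminoacyl-tRNA synthetases, which charge tRNAs, 11 rose and none fell (14 adjusted over the list alone), led by Hars (1.91-fold), Nars (1.48-fold), Lars (1.38-fold) and Tars (1.34-fold). The list gave adjusted p = 6.01e-05, and adjusted p = 0.302 with an estimated correlation, and 7 rose without low glucose replicate 1 or 3. None was lower at an unadjusted p under 0.05 in edgeR, nor by DESeq2 or limma-voom. Of 7 measured transcripts reported as substrates of IRE1α-dependent decay, Hgsnat rose 1.41-fold and no other passed in edgeR, DESeq2 or limma-voom, with 1 lower at an unadjusted edgeR p under 0.05 (adjusted p of the list 0.266; 1 rose adjusted over the list alone, 2 rose and 1 fell with the replicate block, and 2 rose without high glucose replicate 4 or low glucose replicate 2).

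Vesicle coats between ER and Golgi were higher too. Of 28 COPII coat and ER exit genes, 15 rose and 1 fell (16 rose adjusted over the list alone), with a median log2 fold change of 0.32. The cargo receptor subunits Mcfd2 and Lman1 rose 1.82-fold and 1.59-fold, Sec23b, a coat subunit, 1.68-fold and the GTPase gene Sar1a 1.56-fold. The member that fell was Trappc3 (1.19-fold), which did not pass without high glucose replicates 1, 3 or 4 or low glucose replicate 4 (adjusted p 0.0985, 0.0855, 0.102 and 0.0894). This list alone kept its call with an estimated correlation (adjusted p = 2.12e-07 preset, adjusted p = 0.0295 estimated). Of 30 genes of the COPI coat and its retrograde cargo receptors, 21 rose and none fell (22 adjusted over the list alone), with a median log2 fold change of 0.40. Tmed3, a p24 cargo receptor gene, rose 2.65-fold, Kdelr3, a receptor that returns ER residents, 2.53-fold, Arfgap3 1.55-fold and Arcn1, the δ subunit of the coat, 1.52-fold. Its adjusted p was 2.26e-08, and the adjusted p with an estimated correlation was 0.300. No member was lower at an unadjusted p under 0.05 in edgeR, nor by DESeq2 or limma-voom.

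Of 49 genes for Golgi structure and tethering, 22 rose and 1 fell (22 and 1 also adjusted over the list alone), but the median log2 fold change was only 0.15. Bet1, a SNARE of ER to Golgi transport, rose 1.98-fold, Yipf5 1.73-fold, Uso1, the tether p115, 1.58-fold and Cog6, a subunit of the COG tether, 1.47-fold, while Rab6b, a Golgi GTPase gene, fell 1.2-fold. The list gave adjusted p = 5.02e-05, and adjusted p = 0.302 with an estimated correlation. With library size alone as scaling 14 rose and 2 fell, with the replicate block 24 rose and 4 fell, 3 fell without low glucose replicate 2, and none fell without high glucose replicates 3 or 4 or low glucose replicates 1 or 3 (Rab6b adjusted p 0.0606, 0.0538, 0.0586 and 0.0518). Of 37 Golgi glycosylation enzymes and transporters, 4 rose and 7 fell (the same counts adjusted over the list alone), and 4 fell without high glucose replicate 3 or low glucose replicate 4. The nucleotide sugar transporter genes Slc35c1 and Slc35a2 rose 1.65-fold and 1.59-fold and Mgat2 1.49-fold, while Mgat3, which adds bisecting N-acetylglucosamine, fell 1.51-fold. That list was not called (adjusted p = 0.887), and its median of 0.01 and its test differed in sign. The difference between the structure and glycosylation lists was not tested.

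**Figure D3:**
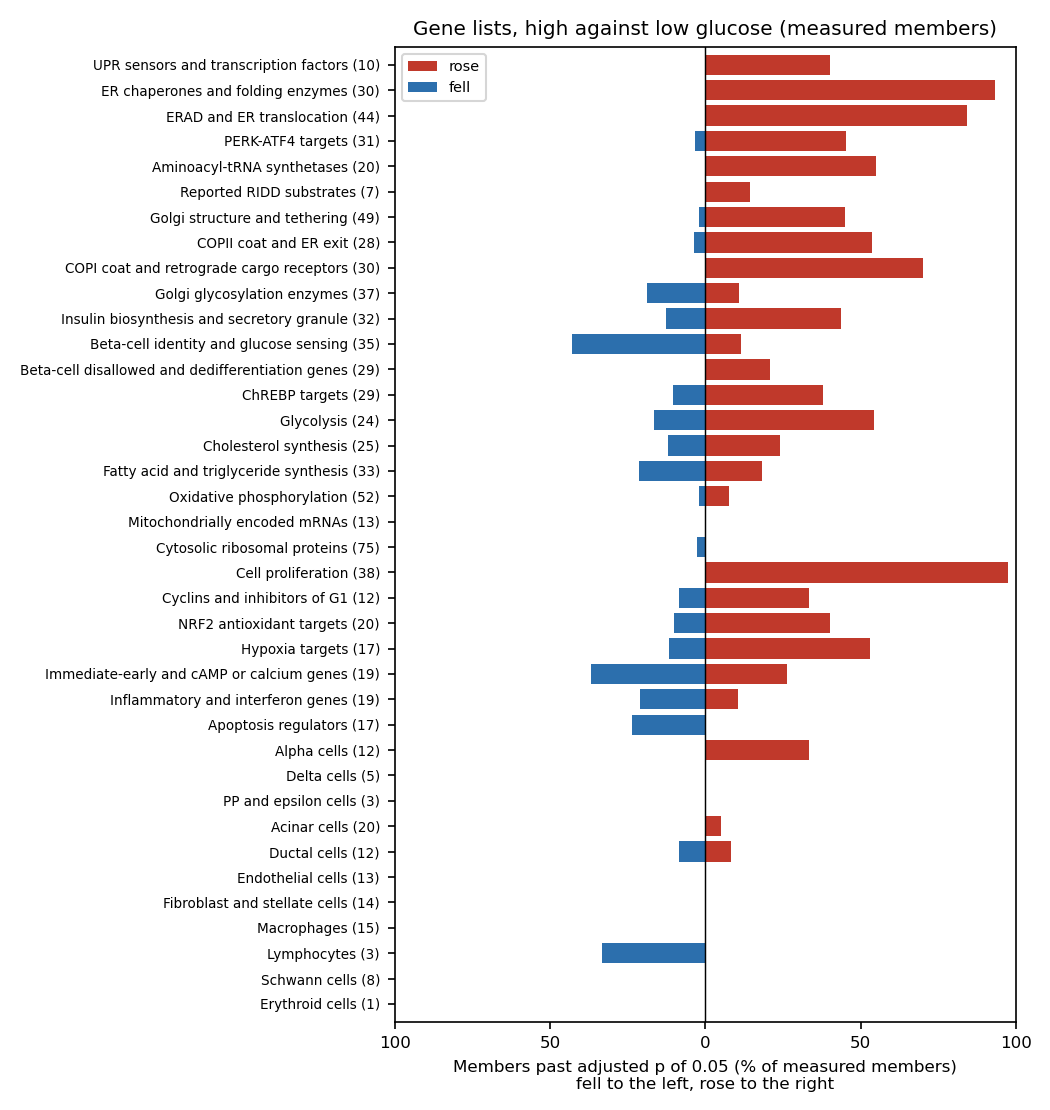
Share of measured members of each of 38 gene lists (y axis, number measured in brackets) that passed adjusted p of 0.05, as a percentage (x axis), with members that rose in red to the right and members that fell in blue to the left. Cell proliferation (37 of 38), ER chaperones (28 of 30) and ERAD and translocation (37 of 44) have the highest shares that rose, and β-cell identity (15 of 35) the highest share that fell.

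Differences in insulin transcripts were within their spread, while several granule genes rose. Ins2 (ENSMUSG00000000215, chromosome 7, 142678656 to 142743381) was at 160600 ± 24924 CPM in high and 153600 ± 32412 CPM in low glucose, a log2 fold change of 0.06 ± 0.16 (SE) with adjusted p = 0.802. Ins1, whose sequence is close to that of Ins2, had a log2 fold change of 0.35 ± 0.18 (SE) with adjusted p = 0.20, and adjusted p = 0.00406 with the replicate block. Iapp, which encodes the co-secreted amylin and overlaps Slco1a5, rose 1.63-fold. Of 32 insulin biosynthesis and granule genes, 14 rose and 4 fell (the same counts adjusted over the list alone), with a median log2 fold change of 0.22. Vgf, a granin, rose 6.04-fold from 41.2 ± 8.58 to 249 ± 44.8 CPM, and Ptprn, a granule membrane protein gene (2.42-fold), Rab3d (2.08-fold) and Hid1 (2.02-fold) rose as well. Sort1 fell 1.39-fold, and Chga, which encodes chromogranin A, fell 1.33-fold. The list had adjusted p = 0.00302, and adjusted p = 0.532 with an estimated correlation. Its count of members that fell was 1 without high glucose replicate 1 or 4 and 2 without high glucose replicate 3 or low glucose replicate 4, and Chga had adjusted p 0.0742, 0.0548 and 0.0674 without high glucose replicates 1, 3 and 4.

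Genes of β-cell identity and glucose sensing were lower on balance. Of 35 measured members, 15 fell and 4 rose (17 and 4 adjusted over the list alone), with a median log2 fold change of -0.18. Slc2a2, which encodes the glucose transporter GLUT2 (ENSMUSG00000027690, chromosome 3, 28697903 to 28731359), fell 1.44-fold from 833 ± 47.1 to 580 ± 66.0 CPM. The transcription factor gene Mafa fell 1.38-fold, the maturity marker Ucn3 1.74-fold, the channel gene Trpm5 2.35-fold and Mlxipl, which encodes the glucose-responsive factor ChREBP, 2.24-fold. G6pc2, the islet glucose-6-phosphatase subunit, rose 1.93-fold and the prolactin receptor gene Prlr 1.74-fold. Pdx1, a β-cell transcription factor gene, was at 219 ± 20.8 and 209 ± 15.2 CPM with adjusted p = 0.611. The list was called with adjusted p = 0.0133, but with adjusted p = 0.561 under an estimated correlation and adjusted p = 0.0522 without high glucose replicate 4. Of 29 genes that mature β cells keep low or that mark dedifferentiation, 6 rose and none fell (6 adjusted over the list alone), with a median log2 fold change of 0.39. Fibroblast and stellate markers had a median of 0.73 (list adjusted p = 0.0875) and acinar markers one of 0.63 (adjusted p = 0.110, and 0.00093 with the replicate block, where 13 rose). Among the 6 were the peptide hormone genes Gast (8.22-fold) and Cck (6.78-fold), both at about 2 CPM in high glucose, Ldha, which encodes lactate dehydrogenase and has processed copies (2.33-fold), and Aldh1a3 (2.12-fold). The list gave adjusted p = 0.00684, adjusted p = 0.566 with an estimated correlation and 0.0551 with fry. None was lower at an unadjusted p under 0.05 in edgeR, nor by DESeq2 or limma-voom.

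Glucose-metabolic genes moved in both directions. Of 29 ChREBP targets, 11 rose and 3 fell (also adjusted over the list alone; 13 and 5 with the replicate block). Besides Txnip, its relative Arrdc4 rose 3.63-fold and Rgs16 3.72-fold, while Khk, the fructokinase gene, fell 2.87-fold. The list had a median log2 fold change of 0.16 with adjusted p = 0.00865, and adjusted p = 0.132 with an estimated correlation. Of 24 glycolysis genes, 13 rose and 4 fell (also adjusted over the list alone), among them Pfkfb3 (2.64-fold), and Pgk1 (2.35-fold) and Eno1 (2.26-fold), which have pseudogene copies. Eno2 and Pfkfb2 fell 1.62-fold and 1.58-fold. Its median was 0.44 with adjusted p = 0.0108, and adjusted p = 0.537 with an estimated correlation. Of 17 hypoxia targets, 9 rose and 2 fell (also adjusted over the list alone), with Egln3 at 4.37-fold, Pdk1 at 1.95-fold, P4ha1 at 1.84-fold and P4ha2 at 1.67-fold, while Vegfa fell 1.40-fold and Ndrg1 1.23-fold. That list had adjusted p = 0.0114, and adjusted p = 0.574 with an estimated correlation, was not called with both libraries numbered 2 left out (adjusted p = 0.0762), and 1 member fell without high glucose replicates 1, 2 or 3 or low glucose replicate 4 (Ndrg1 adjusted p 0.0912, 0.0579, 0.0979 and 0.0934).

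Lipid, respiratory and ribosomal lists moved little or depended on the libraries. Of 25 cholesterol synthesis genes 6 rose, among them Sqle (1.43-fold), Ebp (1.48-fold) and Dhcr7 (1.33-fold), and 3 fell, among them Srebf2 (1.47-fold), with adjusted p = 0.797 for the list. Adjusted over the list alone 6 rose and 5 fell, and 6 fell with the replicate block or without high glucose replicate 1, and 5 without low glucose replicate 2. Of 33 genes for fatty acids and triglycerides 6 rose and 7 fell (also adjusted over the list alone), with Pemt up 3.45-fold, Elovl1, which overlaps the cell cycle gene Cdc20 (log2 fold change 2), up 1.43-fold, Acsl3 down 1.49-fold and Pcyt2 down 1.46-fold, and the list was not called (adjusted p = 0.681, with median 0.01 and a test in the other direction). Of 52 nuclear genes of oxidative phosphorylation, 4 rose, among them Ndufa1 (1.89-fold) and Uqcrq (1.58-fold), and Sdha fell 1.27-fold (3 and 1 adjusted over the list alone), with adjusted p = 0.0875 for the list. With the replicate block that list was called (adjusted p = 0.0184, 16 rose and 3 fell), as it was without high glucose replicate 1 (adjusted p = 0.0238) without low glucose replicate 2 (adjusted p = 3.16e-06, 23 rose) and with the acinar share as a covariate (adjusted p = 0.0373). None of the 13 mitochondrially encoded mRNAs passed in edgeR (adjusted p = 0.677), either over all genes or adjusted over the list alone, none reached an unadjusted p under 0.05 and none passed in DESeq2 or limma-voom. In that list, 1 rose without low glucose replicate 1. The list was called with both libraries numbered 1 left out (median 0.295, adjusted p = 0.0308). Among 75 cytosolic ribosomal protein genes, many with processed copies, Rps27 and Rps3a1 fell 1.52-fold and 1.33-fold and none rose in edgeR (none passed adjusted over the list alone). At an unadjusted p under 0.05, 1 was higher and 11 lower, DESeq2 called 1 higher and 8 lower, and limma-voom 1 and 2. That list's call (median -0.18, adjusted p = 0.0113) was lost with an estimated correlation (adjusted p = 0.933) and without high glucose replicate 1 or 3 or low glucose replicate 2 (adjusted p 0.0862, 0.111 and 0.564). With fry its adjusted p was 0.553. Its count of 2 became 32 with the replicate block, where 1 rose, 12 with library size alone as scaling and 0 to 4 as single libraries were left out. The counts were 0 without high glucose replicates 1, 2 or 3, 1 without low glucose replicates 1, 2 or 4 and 4 without low glucose replicate 3. Rps27 had adjusted p of up to 0.0946 without high glucose replicates 1, 2 or 3 or low glucose replicate 1, and Rps3a1 of up to 0.124 without any 1 high glucose library or low glucose replicates 2 or 4.

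Cell cycle genes gave the highest share of rising members. Of 38 proliferation genes, 37 rose and none fell (38 adjusted over the list alone), with a median log2 fold change of 1.67. Top2a, the topoisomerase of dividing cells, rose 5.29-fold from 6.74 ± 1.58 to 35.8 ± 6.77 CPM, and the replication genes Cdc6, Mcm5 and Mcm2 rose 7.91-fold, 4.4-fold and 2.19-fold. The list gave adjusted p = 1.01e-23, and adjusted p = 0.144 with an estimated correlation. None was lower at an unadjusted p under 0.05 in edgeR, nor by DESeq2 or limma-voom. Ccnd1 and Ccnd2, the D-type cyclins, rose 2.01-fold and 1.45-fold, Cdkn2c 1.82-fold, and Cdkn1b, which encodes the inhibitor p27, fell 1.26-fold. The list of 12 G1 cyclins and inhibitors was not called (adjusted p = 0.159), with 4 members up and 1 down, 6 and 2 adjusted over the list alone, and 7 and 2 with the replicate block. Fibroblast and stellate markers, of which none of 14 passed in edgeR (3 were higher at an unadjusted p under 0.05, and 1 rose in DESeq2), had a median log2 fold change of 0.73, with adjusted p = 0.0875 for the list.

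Immediate-early genes divided into both directions. Of 19 measured immediate-early, cAMP or calcium response genes, 7 fell and 5 rose (8 and 5 adjusted over the list alone). Egr1 (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984) fell from 497 ± 62.8 to 81.1 ± 19.8 CPM, Fos fell 3.05-fold and Junb 3.04-fold, whereas Crem, which encodes a cAMP-responsive factor and repressor, rose 2.49-fold and the phosphodiesterase gene Pde10a 2.29-fold. The list as a whole was not called (adjusted p = 0.735), its median being 0.27, its mean -0.12 and its test directed downward. Of 20 NRF2 antioxidant targets 8 rose, among them Hmox1 (1.90-fold), Srxn1 (1.71-fold) and G6pdx (1.44-fold), and 2 fell, Gstm1 (1.98-fold) and Ftl1 (1.5-fold), both with close relatives or copies. Adjusted over the list alone 10 rose and 2 fell, and the list had adjusted p = 0.0527, adjusted p = 0.0443 with the replicate block, 0.0319 without high glucose replicate 1, 0.0337 without low glucose replicate 4 and 0.0373 with the acinar share as a covariate. Of 17 apoptosis regulators 4 fell and none rose (also adjusted over the list alone), among them Bcl2l11 (1.83-fold), Bid (1.60-fold) and Casp9 (1.34-fold), with adjusted p = 0.681. Casp9 is uncertain, as it overlaps Cela2a, an acinar enzyme gene at 683 CPM in high glucose. None was higher at an unadjusted p under 0.05 in edgeR, nor by DESeq2 or limma-voom. Casp9 had adjusted p of up to 0.0874 without any of high glucose replicates 1 to 3 or low glucose replicates 3 and 4. In that list 1 member rose with the replicate block or without low glucose replicate 2, and its median of 0.08 and mean of -0.05 differed in sign. Of 19 inflammatory and interferon genes Mx1 (3.35-fold) and Rsad2 (2.06-fold) rose, and 4 fell, among them Irf7 (1.91-fold) and Irf1 (1.35-fold), with adjusted p = 0.820, a median of -0.14 and a mean of 0.08. Adjusted over the list alone 3 rose and 5 fell, 4 rose with the replicate block or without low glucose replicate 2, 2 fell without high glucose replicate 3 or low glucose replicate 1, and 1 without high glucose replicate 4. Irf1 had adjusted p 0.0578 and 0.0624 without high glucose replicates 3 and 4.

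Markers of other islet and pancreas cells showed few changes. Gcg, the glucagon gene of α cells, was at 16926 ± 5069 and 19298 ± 6290 CPM (adjusted p = 0.626), while 4 of 12 α-cell markers rose, Gc (6.02-fold), Ptger3 (2.46-fold), Etv1 (1.83-fold) and Ttr (1.66-fold), with adjusted p = 0.174 for the list (4 adjusted over the list alone, 1 fell with the replicate block, and 2 rose without low glucose replicate 1 or 3). At an unadjusted p under 0.05, 1 α-cell marker was lower in edgeR, and DESeq2 called 1 lower and limma-voom none. Ttr had adjusted p of up to 0.0666 without high glucose replicate 2 or low glucose replicates 1, 3 or 4, and Ptger3 of up to 0.124 without high glucose replicates 1 or 4 or low glucose replicates 1, 2 or 3. Ptger3 had adjusted p 0.0668 with library size alone. Sst, the somatostatin gene of δ cells, had a log2 fold change of 0.65 ± 0.23 (SE) with adjusted p = 0.0628, adjusted p = 2.98e-05 with the replicate block and 0.00184 without low glucose replicate 2 and 0.0466 with limma-voom. None of 5 δ-cell markers, which include Rbp4 (132 and 130 CPM), passed in edgeR (list adjusted p = 0.773; 1 was higher and 1 lower at an unadjusted p under 0.05, DESeq2 called none and limma-voom 1 higher; 1 rose and 1 fell with the block or without low glucose replicate 2). Ppy and Pyy of the 3 PP and ε-cell markers were at 2112 ± 373 against 2636 ± 977 CPM and 1232 ± 306 against 1263 ± 352 CPM, and none passed in edgeR, DESeq2 or limma-voom or at an unadjusted p under 0.05 (adjusted p = 0.681). Of 20 acinar markers only Bhlha15, a factor of secretory cells, rose (2.02-fold, with 1 adjusted over the list alone and none lower at an unadjusted p under 0.05), and the digestive enzyme genes Ctrb1 and Pnliprp1 were at 4296 ± 3245 against 2628 ± 1883 CPM and 1486 ± 1292 against 1021 ± 771 CPM. That list was not called (median 0.63, adjusted p = 0.110), but was called with the replicate block (adjusted p = 0.00093, 13 rose; Ctrb1 adjusted p = 0.00228, Pnliprp1 0.0391), with library size alone (0.033) and without high glucose replicate 2 or 3 or low glucose replicate 1 or 4 (0.0236, 0.0283, 0.0294 and 0.0114).

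**Figure D4:**
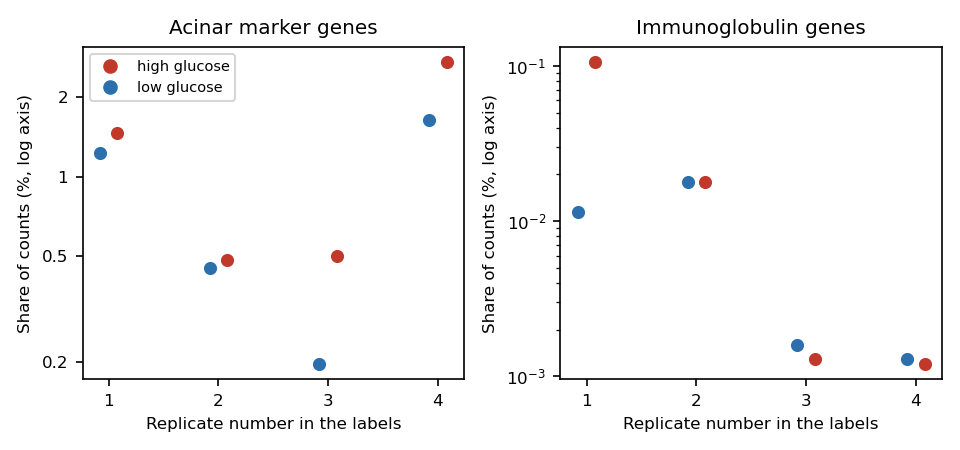
Share of counts (y axis, %, log scale) taken by 22 acinar marker genes (left) and by immunoglobulin genes (right) against the replicate number in the labels (x axis), blue for low and red for high glucose. The acinar share runs from 0.196% to 2.72% and is higher in high glucose in each same-number pair, and immunoglobulin transcripts are highest in high glucose replicate 1, at 0.106%.

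Among 12 ductal markers 1 rose, Spp1 (1.58-fold), and 1 fell. Krt8 and Krt7 were at 385 ± 160 against 286 ± 115 CPM and 270 ± 22.2 against 278 ± 19.6 CPM, and the list was not called (adjusted p = 0.773). With the replicate block 5 ductal markers rose (Krt8 adjusted p = 0.000312), and none rose without low glucose replicate 1 or any 1 of the high glucose libraries. Spp1 had adjusted p of up to 0.104 without any of these or low glucose replicate 4, and 0.0624 with library size alone. Adjusted over the list alone, none rose and 1 fell. No endothelial marker of 13 passed in edgeR (Eng 9.65 ± 1.77 against 8.92 ± 1.84 CPM and Esam 8.53 ± 0.504 against 9.12 ± 1.26 CPM, list adjusted p = 0.922, median 0.06, mean -0.01), nor in DESeq2 or limma-voom, with 1 higher and 1 lower at an unadjusted p under 0.05, and 1 rose without low glucose replicate 2. The fibroblast genes Col1a1 and Col3a1 were at 152 ± 150 against 65.8 ± 34.7 CPM and 148 ± 150 against 57.1 ± 30.9 CPM. The fibroblast list was called without high glucose replicate 4 (adjusted p = 0.00248, 2 rose), without low glucose replicate 3 (0.039, 2 rose), with library size alone (0.0332) and with the acinar share as a covariate (0.0256), and 2 rose with the replicate block and 1 without low glucose replicate 2. No macrophage marker of 15 passed in edgeR (1 higher and 1 lower at an unadjusted p under 0.05, 1 higher in DESeq2; Lyz2 135 ± 30.9 against 138 ± 37.4 CPM, C1qa 95.9 ± 16.4 against 113 ± 25.9 CPM, list adjusted p = 0.821, median -0.03, mean 0.03), though 2 rose and 3 fell with the block (C1qa adjusted p = 0.0387) and 1 rose without high glucose replicate 4 or low glucose replicate 2. Of 3 measured lymphocyte markers Cd79a fell 2.74-fold, and Ighm and Igkc were at 137 ± 233 against 30.9 ± 40.1 CPM and 61.6 ± 99.3 against 13 ± 16.1 CPM (list adjusted p = 0.449, test downward against a median of 2.15, Igkc adjusted p = 0.0184 with the block). No Schwann cell marker of 8 passed in edgeR, DESeq2 or limma-voom or at an unadjusted p under 0.05 (Ngfr 13.3 ± 1.38 against 9.03 ± 3.32 CPM, list adjusted p = 0.451, Ngfr adjusted p = 0.0158 with the block), and the only measured erythroid marker, Alas2, was at 0.481 ± 0.156 against 0.358 ± 0.224 CPM.

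Of the 37 lists tested, 15 were called with the preset correlation, 13 upward and 2 downward, and 1 of these, the COPII list, with an estimated correlation. Without the pairing, no difference beyond the spread between libraries was seen in depth (exact permutation test, two-sided, p = 0.486), insulin share (exact p = 0.743), mitochondrial share (1.45% ± 0.185 against 1.41% ± 0.331, exact p = 0.771) or acinar share (1.29% ± 1.06 against 0.88% ± 0.67, exact p = 0.486). By same-number pairs the acinar share was higher in high glucose in 4 of 4, with an exact paired permutation p of 0.125, the smallest that 4 pairs allow, and the acinar list was called with the replicate block (adjusted p = 0.00093, 13 rose). Paired values for depth, insulin and mitochondrial share were p = 0.625, 0.375 and 0.875 (exact permutation test). In the authors' deposited comparison, 4190 genes passed an adjusted p of 0.05, 2233 of them higher and 1957 lower in high glucose. The refit called 3802 of the same genes, with the same direction for all 3802, while 52 genes passed only in the edgeR fit and 325 tested genes only in the authors' deposited table.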

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

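The tests of patterns here were chosen before the values they measure were looked at, except the test of the genes that ERK signalling induces and that of single replicate pairs, which were chosen after the results were seen. The acinar covariate, and the gene length and GC content trends combined with the replicate block, were themselves settings added after the data were seen.

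A value counted as far from the others where its gap to the nearest of the other 3 libraries of its group exceeded, as a share of the group's range, Dixon's 95% critical value for 4 values, and 26 values among 348 groups met this, where chance gives about 1 in 20. Low glucose replicate 2 held 12 of the 26, against 1 to 4 in each other library. Among library measures, low glucose replicate 1 had the largest total (24949515 counts, or 25 M), low glucose replicate 2 the largest share in the 20 most abundant genes (33.3%) and high glucose replicate 1 the largest immunoglobulin share (0.106%). In low glucose replicate 2, CPM stood apart for Ddit3 (29.8), Ins2 (202000), Iapp (23900), Reln (4.5), Sar1a (275), Lman1 (371), Tmed3 (260), Arcn1 (289), Rps27 (402), Cdkn1b (116) and C1qa (152). In high glucose replicate 2, it did for Tmed3 (623), Slc35c1 (63.4), Dhcr7 (22.9) and Ttr (1660). In high glucose replicate 1 these were Col3a1 (370) and Ighm (483), in replicate 3 Eng (12.3) and in replicate 4 Egr1 (110) and Mgat2 (101). In low glucose they were also Fmo2 in replicate 1 (11.9), Ngfr in replicate 3 (4.12) and Ins1 in replicate 4 (25300).

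The genes of ER folding, translocation and degradation were higher in each high glucose library than in any low glucose library, with list means of 7.82 to 7.95 against 7.09 to 7.22 log2 CPM. RNA of acinar cells, which are rich in such transcripts, is argued against as the whole cause, since with the log2 acinar share as a covariate the group difference was 0.757 (95% interval 0.653 to 0.861) against 0.746 without it. Gene length and GC content bias is argued against as well, since with both trends removed in the blocked fit the median was 0.637 (0.682 before) and 68 of the 74 members still rose. A response of the endocrine cells to 72 h of high glucose may account for the pattern, which is a hypothesis found and tested on the same data. Differences in culture or harvest that went with glucose were not recorded and stay open.

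Genes of cell proliferation were higher in each high glucose library, with list means of 3.22 to 3.68 against 1.66 to 2.18 log2 CPM. More fibroblasts and stellate cells are argued against as the whole cause, since with their marker score as a covariate the group difference was 1.465 (1.051 to 1.879) against 1.531 without it. With the ductal score as a covariate it was 1.505 (1.094 to 1.915), which argues against more ductal cells as the whole cause. Neither fit uses the pairs. The ductal score was higher in high glucose in each same-number pair, and 5 ductal markers rose with the replicate block. Whether more cells divided was not measured, and which cells raised these transcripts stays open in bulk RNA. Division of β cells may be part of it.

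Of the immediate-early genes, 7 fell with a median log2 fold change of -1.601, led by Egr1. If a stress response to handling at harvest also moved heat shock genes, these would be lower too. Their group difference was 0.083 (-0.122 to 0.289), and so lay above -0.801, the midpoint between 0 and that fall. That fall is the median of members chosen because they fell, while all measured heat shock genes were averaged. The mark was therefore easy to pass, and the comparison cannot decide whether handling played a part. Handling that leaves heat shock genes unchanged was not tested and stays open. A difference in a few replicate pairs is argued against, since the members that fell in a fit without a pair fell in that pair too, with a median of -1.322 in the pair with the smallest fall. For lower ERK signalling, gene families linked to ERK feedback were measured (17 genes, 10 rose, and Dusp1, itself 1 of the 7, fell). Their group difference was 0.635 (0.509 to 0.762), above 0. Values of several members had been seen before this test was chosen, so it cannot decide the question. The time from the last medium change to harvest is not given and could matter, and was not tested.

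Splits of the 8 libraries into other groups of 4 tested chance, with 35 splits, the real one included. For the genes changed, higher, lower and changed at least 2-fold, 1 of the 35 splits, the real one, gave as many, with real values of 3854, 2023, 1831 and 737 and a highest other count of 3 for each. That highest count came from a split that kept all same-number pairs together, and the highest among the other splits that part all 4 pairs was 0. For the number of gene lists called, 5 of the 35 splits gave as many (real value 15, highest other 20), so chance cannot be excluded for that number. For 11 lists 1 of 35 splits, the real one, had an absolute median as large, though by a narrow margin for Golgi structure and β-cell identity. These were ER chaperones (0.84, highest other 0.495), ERAD (0.614, 0.357), PERK-ATF4 targets (0.485, 0.298), aminoacyl-tRNA synthetases (0.256, 0.172), Golgi structure (0.146, 0.138), COPII (0.32, 0.24), COPI (0.395, 0.299), β-cell identity (-0.179, 0.166), glycolysis (0.438, 0.376), proliferation (1.672, 1.068) and hypoxia targets (0.674, 0.531). Chance cannot be excluded for the granule list (2 of 35, median 0.219, highest other 0.275), the disallowed genes (4 of 35, 0.388, 0.595), the ChREBP targets (3 of 35, 0.157, 0.181) and the ribosomal proteins (14 of 35, -0.177, 0.374). If the numbers pair the libraries, as was assumed, the like splits are the 8 that part all 4 pairs. These are too few for a share under 0.05 for any of these counts and medians, and among them the highest other number of lists called was 17.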

How the results depend on the processing

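The combined block and trend settings, the left-out pairs and the acinar covariate were chosen after the data were seen, and the other alternatives before. No result that passed in the reported fit or in an alternative reversed its direction there. The tests of 8 lists changed direction in an alternative, each time where the list passed neither in the reported fit nor in that alternative. Among them were Golgi glycosylation and the inflammatory genes, which were down with camera and up with directional fry. Some of these lists passed in other alternatives, such as Golgi glycosylation with mixed fry. Genes called both in the reported fit and in an alternative had the same direction in each setting. The 4 gene counts stayed within 1.5 times of their value in 96 comparisons and moved in 15. With each library left out in turn, the count of genes changed ran from 3015 to 5132, the highest without low glucose replicate 2. With at least 5 CPM in 4 libraries, 325 genes changed at least 2-fold, against 737 in the reported fit. The genes tested went from 15442 to 10872 and the genes changed from 3854 to 3479, a smaller fall in proportion. That filter leaves out genes of low count, so many of the 2-fold changes appear to rest on such genes. The replicate block gave 2862 genes lower in high glucose. With gene length or GC content offsets added to the block, 6070 and 6024 genes changed and 3425 and 3407 were lower, and the cause was not tested. Testing against a fold change of 1.2 gave 1774 genes changed, 1071 higher and 703 lower, and an adjusted p of 0.01 gave 2210, 1261 and 949, both being stricter. Without both libraries numbered 1, the counts were 2180, 1214 and 966, and without both numbered 2, 5033 genes changed. Both settings leave out as many libraries, so the number of samples alone does not account for the difference, and the cause was not tested. With the acinar share as a covariate 3594 genes changed.

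An estimated correlation ended the calls of 14 of the 15 lists and left their medians as they were. Among them were ER chaperones (0.84), ERAD (0.614), Golgi structure (0.146), COPI (0.395), the granule (0.219) and β-cell identity (-0.179). The estimates for the lists that lost their call ran from 0.089 to 0.875, above the preset 0.01, except for the ChREBP targets at -0.012. For the COPII list, which kept its call, the estimate rounded to 0. The estimate thus does not account for every lost call, and the cause was not tested. With fry, which does not compare a list with other genes, the sensors of the unfolded protein response passed with a median of 0.128, both directional (adjusted p = 0.037) and mixed (9.25e-06), and Golgi glycosylation passed as mixed (median 0.013, adjusted p = 3.15e-08). The β-cell identity median ran from -0.283 to -0.19 with single libraries left out, and the list was not called without high glucose replicate 4 (-0.195). Over all alternatives the adjusted p of that list ran from 4.26e-07 to 0.561. The lowest came from mixed fry, which takes changes in either direction and so does not test whether the list was lower. Directional fry gave 0.0228, and the highest value came with an estimated correlation. The cause of the other differences was not tested. Calls of the 9 lists on the secretory pathway and β cells were kept in 161 comparisons, gained in 3 and lost in 7. For the other lists these numbers were 478, 34 and 16, and for named genes 2710, 13 and 85. Counts of list members stayed within 1.5 times in 1051 comparisons and moved in 201. Beyond the changes given with each result, the replicate block changed no call of a named gene or list. Alternatives on a pseudocount or on normalized values were not run, since counts were available. In simulated data at this depth, 43.9% of genes changed 1.5-fold were called. Only 200 genes were changed there, against 3854 called in the real fit, which makes the adjusted threshold stricter in the simulation. The share of small changes missed in the real comparison may therefore differ and was not measured.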

Other observations

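The lists of ERK feedback, clock and N-glycan genes were chosen after their values were seen, as was the ERK test, while the heat shock list was written before its values were looked at. The p-values of the ERK feedback, clock and N-glycan lists describe genes whose values were known, so they do not test these patterns.

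Enzymes that build and transfer N-glycans in the ER were higher in high glucose, while Golgi glycosylation genes went both ways. Of 41 measured genes of N-glycan precursor synthesis and transfer, 29 rose and none fell (29 adjusted over the list alone, and 1 fell with the replicate block), with a median log2 fold change of 0.447. Mogs, the glucosidase that trims the first glucose, had a log2 fold change of 1.10, Gmppb of 0.96, Alg5 of 0.90 and Dpagt1, the first enzyme of the pathway, of 0.78. The list gave adjusted p = 1.23e-13 over 41 lists, and adjusted p = 0.083 with an estimated correlation, and 7 of its genes were also on lists fixed before. The Golgi glycosylation list had 4 members that rose and 7 that fell, and the difference between both lists was not tested.

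Of 19 circadian clock genes 12 fell and 1 rose (also adjusted over the list alone), with Per3 at a log2 fold change of -1.54, Dbp at -1.40, Hlf at -1.09, Tef at -0.86 and Nr1d1 at -0.83, while Npas2 rose by 1.63. Arntl (-0.06) and Clock (-0.01), the core activators, did not pass. The list gave adjusted p = 3.71e-05, and adjusted p = 0.0995 with an estimated correlation. Of 13 ERK feedback and ETS target genes 7 rose and none fell (8 adjusted over the list alone), with Etv5 at 2.29, Dusp4 at 1.74, Spry4 at 1.49, Dusp6 at 1.42 and Dusp5 at 0.71, adjusted p = 2.49e-05, and adjusted p = 0.0574 with an estimated correlation. Dusp1, which fell, is not on that list. Over the 17 measured genes of the whole feedback families 10 rose and 1 fell, with a median log2 fold change of 0.392. Of 12 heat shock genes 1 rose, Bag3, and none fell (1 adjusted over the list alone, and 3 rose with the replicate block), with adjusted p = 0.563. No member of the N-glycan, ERK feedback or heat shock lists was lower at an unadjusted p under 0.05 in edgeR, nor by DESeq2 or limma-voom. Of the clock genes 2, and of the ERK feedback genes 1, were also on lists fixed before.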
